A study of Mus musculus with 19 samples.

How the data were processed

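Flow cytometry gave the sorted cells, namely astrocytes, microglia and monocytes, from female C57BL/6 mice at postnatal day 85 with EAE. Per the labels, EAE was induced with 25 µg of the myelin peptide MOG35-55 in complete Freund's adjuvant after intracranial transduction, the central nervous system of each mouse was taken apart, the cell suspension passed a 70 µm filter and 30% Percoll, and RNA was counted by 3′ digital gene expression. The labels give 1 nervous system per mouse, so each library of a cell type was taken as a mouse. They do not say whether libraries of different cell types with the same number came from the same mouse, nor which antibodies were used.

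The authors deposited 1 table per cell type with a normalized signal per gene and library. The submitters' processing notes name BWA 0.7.10, limma 3.34.1 and the genome build mm10 without saying what each was used for, and neither the notes nor the file headers state the counter, the annotation, a filter on low genes or the scaling. The signal in each column was a whole number of counts times a step: 100% of values above 0 came out whole within 0.01 of a count (45664 values in astrocytes, 18589 in microglia and 13747 in monocytes). The geometric mean of the column totals was 1000000 in each table. Recovered counts scaled to a depth of 1000000 with edgeR's trimmed mean of M-values factors equalled the deposited values within a relative difference of 4.48e-10, 4.94e-10 and 4.81e-10. The labels do not say whether a count is a read or a molecule, so these are called counts, and intervals and floors made from them cover counting error only.

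The tables held 6376 genes (astrocytes), 3067 (microglia) and 3776 (monocytes). Gene symbols were kept as deposited. Microglia symbols were in capitals and were matched by letter case to the reference annotation, and older symbols were matched through synonyms. Among the names 15 of astrocytes and 5 of microglia had been turned into dates or serial numbers and were not named. Coordinates are those of GENCODE M21 on GRCm38, the build also called mm10. No 2 libraries were identical: the chi-square per gene between replicates of a group lay between 1.526 and 9.896 over 23 pairs.

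Computation used R 4.3.3 with limma 3.58.1, edgeR 4.0.16 and DESeq2 1.42.0, and Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9. Each cell type was fitted alone, shXbp1 against shScrmbl, with no covariate. Groups, tests, gene lists and alternatives were fixed before the data were examined. The main test was limma with trend and robust empirical Bayes on log2(signal + 1), with Benjamini-Hochberg adjusted p under 0.05. Genes needed a signal of at least 1 in as many libraries as the smaller group had, which left 6366, 3066 and 3775 genes. Folds on this scale depend on the pseudocount for low genes, since 1 count was worth a signal of 4.22 to 76.0. edgeR's quasi-likelihood test and DESeq2 on recovered counts had been planned as second tests, and giving them beside limma throughout was decided after the results were seen. They called 1, 12 and 1 genes (edgeR) and 0, 0 and 0 (DESeq2) in astrocytes, microglia and monocytes. Single-gene and marker comparisons used exact two-sided permutation tests. A fold against a group at 0 was bounded with a floor of 3 counts over the group, and groups with 1 to 3 counts were given an exact binomial interval of the pooled ratio.

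The 25 gene lists covered ER chaperone and ER-associated degradation genes of XBP1 and ATF6, ATF4 and CHOP stress genes, NF-kB and proinflammatory, reactive astrocyte, interferon response, antigen presentation, cholesterol and fatty acid synthesis, oxidative phosphorylation, mitochondrially encoded, ribosomal protein, immediate early, cell cycle, homeostatic and disease-associated microglia, and classical and alternative myeloid genes. They also covered markers of astrocytes, microglia, monocytes and macrophages, neutrophils, lymphocytes (T, NK and B cells), the oligodendrocyte lineage, neurons, endothelial and mural cells, and ependyma and choroid plexus. Lists with at least 5 measured members were tested with limma's camera (preset correlation 0.01), adjusted over the lists of a cell type, and again with an estimated correlation, with fry and with camera on the counts. Single genes were named by a rule: Xbp1, the 8 risen and 8 fallen genes with the smallest adjusted p, or, where fewer than 4 passed, the 4 with the smallest unadjusted p, and up to 4 members of each list described. Genes called by the count test and Apoc2 in every cell type were added after the results were seen. Some genes that the rule names are not reported here.

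The tests were tested on simulated data with the real means, depths and spread, 10 simulations per cell type. Of genes changed 8-fold, edgeR recovered 82.9%, 74.7% and 38.2% in astrocytes, microglia and monocytes, and limma 31.9%, 23.2% and 16.4%. Of genes changed 4-fold edgeR recovered 41.2%, 35.8% and 10.2%, and limma 14.4%, 11.2% and 5.15%. Of genes changed 2-fold neither recovered more than 4.13%. With no change no tool made a call in any simulation. A list of 20 genes drawn from above the median level, each raised 2-fold, was called in 10, 10 and 9 of 10 simulations. Unchanged lists were called in 0 of 230, 1 of 200 and 1 of 200. Lists with low genes or mixed directions were not simulated. Each gene was simulated independently of the others, so these rates do not cover genes that vary together in real libraries. Other splits of the real libraries gave up to 28 edgeR calls in astrocytes and 29 in microglia, and up to 10 and 6 called lists.

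The alternatives were another empirical Bayes setting, array weights, quantile normalization, median centring, no filter, genes above the median level, pseudocounts of 0.5 and 5, a threshold of 0.1 for lists, a replicate block, and each library left out. A pseudocount of 20, counts thinned to the shallowest library (20 draws), count-based overlaps and count-based list tests were added after seeing the data.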

Results

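The series asks how astrocyte Xbp1 shapes expression in astrocytes and in neighbouring myeloid cells during experimental autoimmune encephalomyelitis (EAE), a mouse model of multiple sclerosis. Xbp1 encodes a transcription factor of the unfolded protein response, which raises the protein-folding capacity of the endoplasmic reticulum (ER). Female C57BL/6 mice received a lentivirus in the brain that drives GFP and a short hairpin RNA from the Gfap promoter, which is active in astrocytes. The hairpin either had no target (shScrmbl) or was aimed at Xbp1 (shXbp1), and EAE was then induced with a myelin peptide. RNA of sorted astrocytes (4 shScrmbl and 4 shXbp1 libraries), microglia (4 and 3) and monocytes (2 and 2) was counted at the 3′ ends of transcripts, giving 19 libraries.

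Depth was low and uneven, as the plot of counts per library shows. Astrocyte shScrmbl replicates 1 to 4 held 50392, 302003, 35450 and 32842 counts, and shXbp1 replicates 1 to 4 held 53228, 221367, 85398 and 159189. Microglia shScrmbl replicates 1 to 4 held 17892, 92765, 122002 and 25821 counts, and shXbp1 replicates 1 to 3 held 10039, 13321 and 46586. Monocyte shScrmbl libraries held 74340 and 112676 counts, and shXbp1 libraries 15654 and 56625. A count of 0 allowed a signal of up to 82.7 in the shallowest astrocyte library, up to 228 in microglia and up to 152 in monocytes. Ttr, the transthyretin gene that choroid plexus cells express strongly, made up 14.2% to 26.7% of counts in astrocyte libraries, 1.69% to 6.25% in microglia and 0.343% to 0.945% in monocytes.

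**Figure D1:**
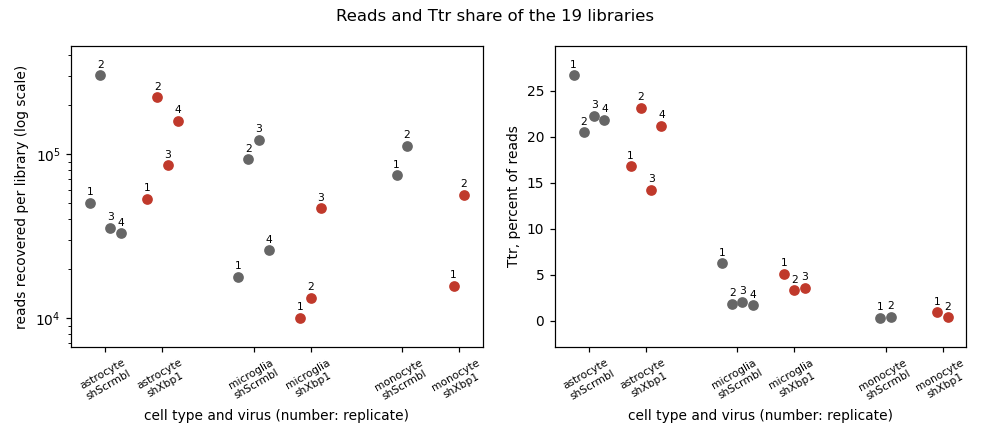
Total counts of each of the 19 libraries (log axis) and the share of counts from Ttr (percent), by cell type and hairpin, with 1 point per library. The deepest library, astrocyte shScrmbl replicate 2, held 302003 counts and the shallowest, microglia shXbp1 replicate 1, held 10039.

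Xbp1 itself (chromosome 11, 5520659 to 5525893, GRCm38) had nearly the same mean in astrocytes with and without the hairpin aimed at it, at a precision that left a wide range open. Its signal was 20.1, 71.7, 79.9 and 27.6 in the 4 shScrmbl astrocyte libraries and 34.1, 52.9, 31.2 and 79.7 in the 4 shXbp1 libraries. The mean was 49.8 ± 30.3 (SD, n = 4) against 49.5 ± 22.3 (n = 4), from 22 and 28 counts. The limma log2 difference was 0.12 (edgeR -0.08), with a 95% interval from -1.33 to 1.57, so that folds from 0.397 to 2.97 remained possible. An exact two-sided permutation test over 3 cell types gave p = 0.971 in astrocytes (adjusted p = 1). In microglia Xbp1 gave 51.9, 50.5, 103 and 0 in shScrmbl and 76.0, 69.0 and 0 in shXbp1 libraries, from 16 and 2 counts, with a pooled ratio of 0.415 (95% counting interval 0.0463 to 1.77) and an exact permutation p of 0.886. Monocyte values were 126 and 182 in shScrmbl and 303 and 126 in shXbp1 libraries, where 2 against 2 libraries allow no permutation p below 0.333. A count at the 3′ end can also come from a transcript that a hairpin has cut upstream, and the labels do not say whether sorted astrocytes were selected for GFP. In astrocytes the pooled ratio of Xbp1 counts was 0.895 (95% counting interval 0.494 to 1.64). No knockdown of the counted transcript was therefore seen in the astrocyte libraries, which also held counts of microglia and choroid plexus markers. Falls below 0.397 of the shScrmbl level lay outside the limma interval, while smaller falls stay open. Every comparison below is between libraries labelled shXbp1 and shScrmbl.

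**Figure D2:**
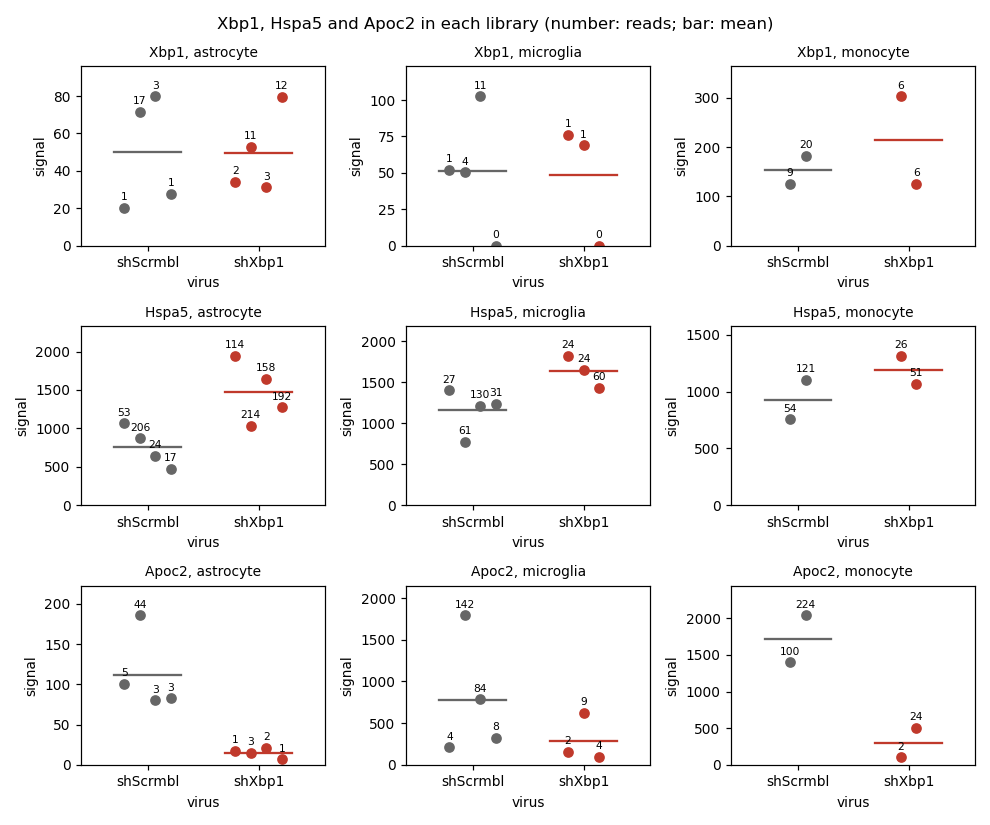
Signal of Xbp1, Hspa5 and Apoc2 in each library of the 3 cell types (points, with the gene's counts written beside them) and the mean of each group (bars). Xbp1 overlapped between the groups in every cell type, while Apoc2 was lower in all 4 shXbp1 astrocyte libraries (mean 14.7) than in any shScrmbl library (mean 112).

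In astrocytes, Apoc2, the apolipoprotein that activates lipoprotein lipase (chromosome 7, 19671579 to 19677941), fell from 112 ± 49.8 with shScrmbl to 14.7 ± 6.00 with shXbp1 (SD, n = 4 and 4; 55 and 7 counts). It fell by 3.11 on the log2 scale in edgeR's quasi-likelihood test (adjusted p = 0.0145), and it was lower in 4 of 4 shXbp1 libraries than in any shScrmbl library. Apoc2 was the single gene that passed a test, and its call ended without either of 2 libraries while the difference stayed near its size. Without shScrmbl replicate 2 edgeR gave -2.61 (adjusted p = 0.781) and without shXbp1 replicate 4 it gave -2.86 (adjusted p = 0.144). On the log2(signal + 1) scale limma gave Apoc2 a difference of -2.86 ± 0.77 (SE) with an adjusted p of 0.824, the smallest adjusted p in the astrocyte table and shared by other genes.

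None of the other astrocyte genes that stood highest passed a test. Hspa5, the ER chaperone BiP and a classic unfolded protein response gene, had 760 ± 260 in shScrmbl and 1473 ± 403 in shXbp1 astrocytes (log2 difference 0.98 ± 0.29 SE). Hsp90aa1, a cytosolic chaperone, had 3763 ± 1233 and 6388 ± 1421. Slc38a1, a glutamine transporter, had 32.0 ± 6.25 and 135 ± 27.3 and lay higher in all 4 shXbp1 libraries. Nelfb, a subunit of the complex that pauses RNA polymerase II, had 7.38 ± 14.8 and 74.4 ± 30.3. At the low end, Creb3, a transcription factor held in the ER membrane, had 138 ± 29.4 and 34.7 ± 24.4. Klf4, an immediate early transcription factor, had 115 ± 43.8 and 34.8 ± 23.2, and Rint1, which acts in transport between the Golgi and the ER, had 245 ± 149 and 90.8 ± 8.37.

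Across 6366 astrocyte genes limma called 0, with 298 at an unadjusted p under 0.05 (263 higher and 35 lower) where chance gives 318. The edgeR test called 1 gene (415 at an unadjusted p under 0.05) and DESeq2 called 0 (131). Without shScrmbl replicate 1 edgeR called 8 genes and without shXbp1 replicate 2 it called 7, each time with Apoc2 among them. Groups did not overlap for 151 genes that were higher and 50 that were lower, which is 3.16% of genes where chance gives 2.86%. The median log2 difference of all genes was 0.42 by limma and 0.05 by edgeR, so gene groups are given against the other genes of the same table (the gap).

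Antigen presentation genes fell as a group in astrocytes. Of the 22 listed genes 17 were measured, 3 with higher and 14 with lower signal in shXbp1 libraries, and the list lay 1.29 below other genes on the log2 scale (gap -1.29, limma camera adjusted p = 5.1e-05, and 0.777 with an estimated correlation, n = 4 and 4). The mean of the list was -0.68 and its median -0.64. H2-Aa and H2-Ab1, the chains of the class II molecule I-A, had 624 ± 533 and 291 ± 220 in shScrmbl against 232 ± 97.0 and 126 ± 27.1 in shXbp1 astrocytes. H2-DMa, which loads peptides on class II, had 111 ± 74.5 and 31.1 ± 31.3, and the class I gene H2-K1 had 428 ± 295 and 249 ± 105. No member passed limma over all genes or adjusted over the list alone, while edgeR called 0 over all genes and 4 adjusted over the list alone. Astrocyte shScrmbl replicate 2 held the most myeloid transcripts (mean log2 of microglia markers 8.40, against 5.26 to 6.55 in the other shScrmbl libraries), and H2-Aa was 1408 there against 221 to 469 in the others. It was also the deepest library, with fewer genes at 0. Against all genes its microglia markers lay at 2.56, with 0.87, 0.53 and 1.94 in shScrmbl replicates 1, 3 and 4. Myeloid markers were lower too on the count scale, with median edgeR differences of -0.80 for 20 microglia and -1.11 for 13 monocyte and macrophage markers, while astrocyte markers were higher (0.77). H2 genes share sequence with near copies, so the reads of single members are uncertain.

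Oxidative phosphorylation and ribosomal protein genes were also called lower than other genes in astrocytes, by smaller gaps. All 40 oxidative phosphorylation genes were measured, 16 higher and 24 lower, with a gap of -0.64 (limma camera adjusted p = 0.045, and 0.777 with an estimated correlation). Ndufs5 and Cox6a1, of respiratory complexes I and IV, had log2 differences of -1.61 and -0.32, and Cox5a and Atp5k had 0.69 and 0.30. Of 44 ribosomal protein genes 43 were measured, 17 higher and 26 lower, with a gap of -0.60 (limma camera adjusted p = 0.045, and 0.777 with an estimated correlation), a mean of 0.01 and a median of -0.02, so that mean and median differed in sign. Rps24 had 850 ± 201 and 1551 ± 674, and Rpl18 and Rps23 had differences of 0.95 and 0.70. Quantile normalization turned the gaps of oxidative phosphorylation and ribosomal protein genes to 0.02 and 0.08, and camera on counts called neither list (adjusted p = 0.267 and 0.357, median edgeR differences -0.02 and -0.02). The oxidative phosphorylation call ended without shScrmbl replicate 1 (adjusted p = 0.386), shScrmbl replicate 3 (0.255), shXbp1 replicate 1 (0.139) or shXbp1 replicate 3 (0.231) by limma camera. Without shScrmbl replicate 3 (0.214), shScrmbl replicate 4 (0.210) or shXbp1 replicate 3 (0.422) the ribosomal call ended in the same test, while the antigen presentation call held without any 1 library (gaps -1.75 to -1.08).

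Genes that XBP1 and ATF6 are known to drive, which encode ER chaperones and the degradation of misfolded ER proteins, were mostly higher without passing the list test. Of 38 listed genes 26 were measured, 22 higher and 4 lower (gap 0.16, limma camera adjusted p = 0.125, and 0.777 with an estimated correlation), and no member passed alone. Beside Hspa5, the ER form of Hsp90 (Hsp90b1) had 963 ± 410 and 1448 ± 203 in shScrmbl and shXbp1 astrocytes, the glycoprotein chaperone calnexin (Canx) 342 ± 164 and 589 ± 229, and the co-chaperone Dnajc3 199 ± 117 and 336 ± 85.7. Camera on the recovered counts did call this list higher (edgeR log counts, adjusted p = 0.00843; 0.334 with an estimated correlation).

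NF-kB genes in astrocytes went different ways by scale. Of 17 measured NF-kB and proinflammatory genes 11 were higher and 6 lower by limma (gap -0.36, limma camera adjusted p = 0.503), and 3 were higher and 14 lower by edgeR (camera on counts adjusted p = 0.0427, downward, and 0.466 with an estimated correlation). The adhesion gene Vcam1 had 138 ± 94.7 and 197 ± 110, the NF-kB inhibitor Nfkbia 152 ± 96.9 and 186 ± 35.2, and the cytokine Csf1 94.2 ± 84.0 and 43.7 ± 9.36. The neutrophil chemokine Cxcl2 had a log2 difference of 1.36 by limma and -0.31 by edgeR. Of 12 measured reactive astrocyte genes 7 were higher and 5 lower (gap -0.42, adjusted p = 0.437 by limma camera). Complement C3 had 72.2 ± 22.4 and 45.3 ± 36.6 and the ferroxidase Cp 24.2 ± 38.0 and 54.3 ± 15.6, while Srgn had 1.76 by limma and -0.22 by edgeR. The LPS co-receptor Cd14, also a myeloid marker, had 165 ± 146 and 89.3 ± 101.

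Microglia of shXbp1 mice had lower values of genes that monocyte-derived cells express strongly. edgeR's quasi-likelihood test called 12 of 3066 genes, 4 higher and 8 lower, among libraries of 4 shScrmbl and 3 shXbp1 mice. Cybb, the catalytic subunit of the phagocyte NADPH oxidase, fell from 819 ± 597 to 222 ± 63.7 (edgeR log2 difference -1.95, adjusted p = 0.0164). Hp, the haemoglobin-binding haptoglobin, fell from 318 ± 329 to 54.0 ± 73.7 (edgeR -3.06, adjusted p = 0.0136; 100 and 3 counts, ratio 0.0997 with a counting interval of 0.0202 to 0.30). Saa3, an acute phase protein of macrophages, fell from 1448 ± 714 to 472 ± 315, and Pla2g7, which breaks down platelet-activating factor, from 547 ± 341 to 71.8 ± 124. Anxa5, a phospholipid-binding annexin, fell from 667 ± 225 to 134 ± 132, and the complement factor Cfb from 511 ± 470 to 126 ± 70.6. Lysozyme genes Lyz1 and Lyz2 fell from 13380 ± 9123 to 4612 ± 3647 and from 11155 ± 7132 to 4133 ± 3193. Lyz1 and Lyz2 share reads with each other, and Saa3, Hbb-bt and Rps24 with near copies, so these 5 are uncertain.

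Among the genes called higher, the ribosomal gene Rps24 rose from 2515 ± 772 to 6244 ± 2188 (edgeR 1.31, adjusted p = 0.0478), the beta-globin gene Hbb-bt from 172 ± 211 to 603 ± 255, and Prss34, a protease of mast cells and basophils, from 132 ± 134 to 490 ± 408. How many calls held, and how large the differences were, depended on the library left out. Without shScrmbl replicate 3 edgeR called 0 genes (Cybb -1.94, adjusted p = 0.135; Hp -3.09, adjusted p = 0.115; Rps24 1.40, adjusted p = 0.239), and without shScrmbl replicate 2 Cybb had -1.37, Hp -2.22, Cfb -1.57 and Lyz2 -0.98 (adjusted p of 0.914 or more). Without shScrmbl replicate 2 or shXbp1 replicate 1 edgeR called 1 (Prss34), and without shXbp1 replicate 3 it called 5, of which 4 were among the 12. Prss34 leaned on single libraries, with 0.73 (edgeR adjusted p = 0.939) without shXbp1 replicate 3 and 3.22 without shScrmbl replicate 2. Without shScrmbl replicate 1 edgeR called 23 genes, 11 of them among the 12, without shScrmbl replicate 4 it called 16 with all 12 kept, and without shXbp1 replicate 2 it called 11, 7 of them among the 12. Differences of Anxa5 and Pla2g7 grew without shXbp1 replicate 3 and that of Hp without shXbp1 replicate 2, where 2, 0 and 1 counts of these genes were left in shXbp1 libraries.

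By limma no microglia gene passed (0 of 3066, smallest adjusted p = 0.653), with 166 at an unadjusted p under 0.05 (20 higher and 146 lower) where chance gives 153. Without shScrmbl replicate 1 limma called 3 genes, each lower. DESeq2 called 0 (62 at an unadjusted p under 0.05), and edgeR had 168. Groups did not overlap for 71 genes that were higher and 151 that were lower, or 7.24% where chance gives 5.71%. The genes with the smallest p by limma included the lysosomal protease Ctsb (10735 ± 2930 and 4597 ± 2148), the actin regulator Arpc1b (716 ± 95.4 and 250 ± 124) and the ATP synthase subunit Atp5e (633 ± 175 and 230 ± 167). Ptgds, a prostaglandin D2 synthase that oligodendrocytes and meninges express, had 278 ± 171 and 753 ± 220, and Ssh2, a cofilin phosphatase, had 120 ± 56.6 and 343 ± 61.5. All genes together had a median log2 difference of -0.39 by limma and -0.09 by edgeR.

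Homeostatic microglia genes, which mark resting resident microglia, rose as a group against other genes. All 20 were measured, 15 higher and 5 lower (gap 1.19, limma camera adjusted p = 0.00259, and 0.715 with an estimated correlation, n = 4 shScrmbl and 3 shXbp1). The mean of the list was 0.44 and its median edgeR difference 0.42, so much of the gap came from lower values of the other genes. The median of all genes was -0.39 by limma and -0.09 by edgeR. With thinned counts limma camera called 0 microglia lists. Tmem119 had 344 ± 140 in shScrmbl and 623 ± 187 in shXbp1 microglia, the purine receptor P2ry12 490 ± 344 and 730 ± 261, Gpr34 115 ± 35.3 and 214 ± 62.0, and the fractalkine receptor Cx3cr1 1361 ± 204 and 1932 ± 369. Monocyte and macrophage markers fell, with 2 of 18 measured genes higher and 16 lower (gap -1.20, limma camera adjusted p = 0.0161, and 0.715 with an estimated correlation). Beside Cybb and Hp, the calcium-binding S100a6 had 224 ± 147 and 54.9 ± 49.4. Emr1, the older name of Adgre1 (F4/80), had 185 ± 45.7 and 71.8 ± 124. No homeostatic gene and 1 monocyte marker passed limma adjusted over the list alone, and 0 of either passed limma over all genes. By edgeR 3 monocyte markers passed over all genes and 6 over the list alone, and 0 and 1 homeostatic genes did.

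Antigen presentation and interferon response genes also fell in microglia. All 17 measured antigen presentation genes were lower by limma and 16 by edgeR (gap -0.32, limma camera adjusted p = 0.014, and 0.715 with an estimated correlation). Camera on counts gave an adjusted p of 5.9e-07 (0.374 with an estimated correlation). By limma 0 passed over all genes and 4 adjusted over the list alone, and by edgeR 0 and 0. Against all genes shXbp1 replicates 1, 2 and 3 lay at -0.01, -0.09 and -0.84 from the shScrmbl mean, with shScrmbl libraries at -0.33 to 0.33. On this scale most of the gap therefore came from shXbp1 replicate 3, but the signals of the 4 members named next were highest there. B2m had 4788, 4622 and 7877 in shXbp1 replicates 1, 2 and 3, and Tapbp 152, 207 and 407. In replicates 1 and 2, 32.7% and 25.6% of genes were at 0, against 3.16% in replicate 3. Zeros lower the mean of all genes, so this scale does not show which library lowered the list. B2m, the light chain of class I molecules, had 10481 ± 806 in shScrmbl and 5762 ± 1833 in shXbp1 microglia, H2-Aa 4782 ± 1277 and 2423 ± 1208, H2-DMa 918 ± 124 and 452 ± 355, and the peptide-loading chaperone Tapbp 538 ± 49.1 and 255 ± 134. Of 26 measured interferon response genes 3 were higher and 23 lower (gap -0.99, limma camera adjusted p = 0.0196, and 0.715 with an estimated correlation), with 0 past limma over all genes or adjusted over the list alone. The T cell attractant Cxcl9 had 215 ± 82.9 and 81.6 ± 65.0, the secreted Lgals3bp 1086 ± 408 and 578 ± 241, and the antiviral membrane protein Ifitm3 854 ± 349 and 424 ± 173. Igtp, an interferon-induced GTPase, had 31 and 3 counts (ratio 0.322, counting interval 0.0629 to 1.03). Monocyte and macrophage markers lay lower in the same libraries (mean log2 7.39 ± 1.09 and 5.45 ± 0.66).

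Without shXbp1 replicate 3, the deepest shXbp1 library, no list passed limma camera, with adjusted p = 0.0543 for homeostatic genes and 0.148 for the other 3 lists. The antigen presentation gap then shrank to -0.05, with only the shallowest shXbp1 libraries left, where 32.7% and 25.6% of genes were at 0. Gaps of the homeostatic (1.57), interferon (-1.06) and monocyte marker (-1.05) lists grew or stayed near their size. The interferon call also ended without shScrmbl replicate 3 (0.0683) or 4 (0.0585), and the monocyte marker call without shScrmbl replicate 2 (0.0943).

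Disease-associated microglia genes, a program of microglia that take up debris, were lower for 18 of 25 measured members, including Ctsb, the protease Ctsd (22714 ± 2673 and 14173 ± 3970), the lipid carrier Fabp5 (908 ± 631 and 360 ± 64.8) and Apoe (24912 ± 7672 and 15830 ± 9447). Against other genes the list mean had a gap of 0.42 while its own mean was -0.33, and limma camera gave an adjusted p of 0.925 in the downward direction and camera on counts 0.00999 (0.453 with an estimated correlation); 0 passed limma over all genes and 1 adjusted over the list alone. Of 18 NF-kB and proinflammatory genes 6 were higher and 12 lower (gap -0.30, limma camera adjusted p = 0.978). Tnf had 175 ± 87.8 and 330 ± 52.2, while the monocyte attractant Ccl2 had 42 counts in shScrmbl and 1 in shXbp1 libraries (ratio 0.0791, counting interval 0.00196 to 0.465). Vcam1 had 126 ± 52.4 and 47.9 ± 82.9, and the related attractant Ccl7 had 15 and 3 counts (ratio 0.664, counting interval 0.123 to 2.35).

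Monocytes gave the one gene that both limma and edgeR called. Ccl17, a chemokine that attracts T cells through CCR4 (chromosome 8, 94810453 to 94812036), rose from 66.8 ± 4.33 in shScrmbl to 738 ± 615 in shXbp1 libraries (SD, n = 2 and 2; 12 and 62 counts). It rose by 3.14 ± 0.75 (SE) on the log2 scale by limma (adjusted p = 0.00901) and by 3.52 by edgeR (adjusted p = 0.0102), and it was higher in 2 of 2 shXbp1 libraries. The edgeR call ended without shScrmbl replicate 1 (3.54, adjusted p = 0.9997), shScrmbl replicate 2 (3.36, adjusted p = 0.998) or shXbp1 replicate 2 (2.16, adjusted p = 0.448). The limma call of Ccl17 ended without shScrmbl replicate 1 (3.21, adjusted p = 0.995) or shScrmbl replicate 2 (3.08, adjusted p = 0.992). No other gene was called higher. Cdk2ap2, a cell cycle regulator, had 71.7 ± 37.0 and 273 ± 28.5, and Abhd15 20.6 ± 9.44 and 143 ± 83.8.

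On the log2(signal + 1) scale limma called 100 monocyte genes lower, and 99 of them had no count in either shXbp1 library. They held a median of 11 counts over both shScrmbl libraries. Gdpd1, Nin, Pdlim5, Rabepk and Ugp2 each had 10 counts in shScrmbl and 0 in shXbp1, and Amdhd2, Wdr3 and Zfp444 had 12 and 0. Against a floor of 3 counts over the group, the bound on the fall was 1.24-fold for the first 5 and 1.49-fold for the other 3. Over the 99 genes the bounds ran from 1.12-fold to 2.73-fold (median 1.37), and 9 genes reached a bound of 2 or more. These bounds do not allow for the choice of genes at 0 or for variation between mice. Sampling with no change gave 47.2 tested genes at 0 in both shXbp1 libraries where 101 were seen, so many of these genes need not be lower. The remaining gene called lower was Apoc2, chosen for mention after its values were seen. It fell from 1719 ± 454 to 302 ± 284 (324 and 26 counts; limma -2.90 ± 0.71 SE, adjusted p = 0.0147; edgeR -2.35, adjusted p = 0.333).

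In all, limma called 101 of 3775 monocyte genes with 180 at an unadjusted p under 0.05, where chance gives 189. The edgeR test called 1 (178) and DESeq2 called 0 (21). The shScrmbl libraries held 72.9% of the monocyte depth. With a pseudocount of 20, or with all libraries thinned to the shallowest, limma called 0 genes, and without either shScrmbl library it called 0. Without shXbp1 replicate 1 limma called 486 and without shXbp1 replicate 2 it called 1163. Groups did not overlap for 372 genes that were higher and 945 that were lower, or 34.9% where chance gives 33.3%. The median log2 difference of all genes was -0.42 by limma and -0.17 by edgeR.

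ER chaperone and ER-associated degradation genes rose as a group in monocytes against other genes, as the plot of gene lists shows. Of 24 measured genes 18 were higher and 6 lower (gap 1.45, limma camera adjusted p = 0.000247, and 0.971 with an estimated correlation, n = 2 and 2), with 0 past limma over all genes or adjusted over the list alone. Creld2 had 32.2 ± 5.99 in shScrmbl and 124 ± 32.1 in shXbp1 monocytes, the translocon subunit Sec61a1 64.7 ± 27.1 and 185 ± 24.6, and the degradation factor Derl1 27.6 ± 0.446 and 96.8 ± 77.6. Dnajb11, a co-chaperone of Hspa5, had 20.6 ± 9.44 and 96.8 ± 77.6. These genes rested on few counts. Derl1 had 2 and 3 in the shScrmbl and 3 and 2 in the shXbp1 libraries, Dnajb11 1 and 3 against 3 and 2, and Creld2 2 and 4 against 2 and 7. Ribosomal protein genes rose too, with 39 of 43 higher and 4 lower (gap 1.28, limma camera adjusted p = 6.9e-05, and 0.971 with an estimated correlation) and again 0 past limma over all genes or adjusted over the list alone. Rpsa had 2774 ± 8.95 and 4471 ± 756, Rplp1 1369 ± 98.4 and 2171 ± 67.8, Rps29 1361 ± 304 and 2239 ± 950, and Rps24 2831 ± 169 and 6200 ± 4407. By edgeR the median differences were 0.44 for the ER list and 0.38 for the ribosomal list against -0.17 for all genes, much less than the gaps, and on the limma scale the list means were 0.48 and 0.30. The ER call ended without shXbp1 replicate 1 (limma camera adjusted p = 0.0634) and the ribosomal call without shXbp1 replicate 2 (0.30).

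**Figure D3:**
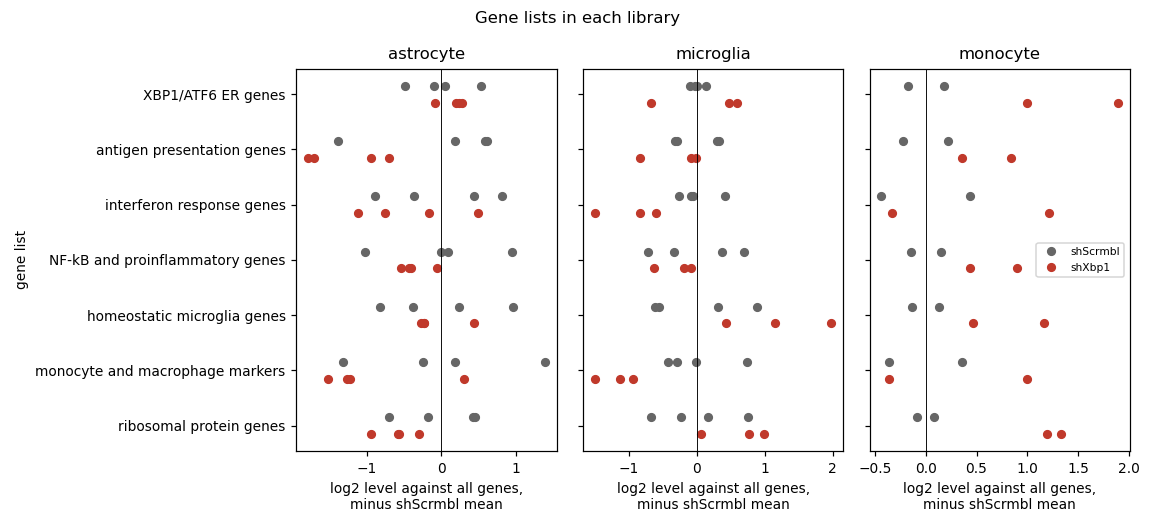
Level of 7 gene lists in each library, as the mean log2 signal of the list minus that of all genes, set to 0 at the mean of the shScrmbl libraries of the same cell type. Points are libraries, and the gaps tested between groups range from -1.29 for antigen presentation genes in astrocytes to 1.45 for ER chaperone genes in monocytes.

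Neutrophil and immediate early genes held 3 of the 4 monocyte list members that passed limma, and Ccl17, of the alternative myeloid list, was the other. Of 10 measured neutrophil markers 3 were higher and 7 lower (gap -1.84, limma camera adjusted p = 0.183, and 0.971 with an estimated correlation; camera on counts downward, 0.0114, and 0.839 with an estimated correlation). The collagenase Mmp8 went from 18 counts to 0 (bound of 2.23-fold against the floor, limma adjusted p = 0.0283). It was the only member past limma over all genes or adjusted over the list alone, while edgeR called 0 over all genes and 3 adjusted over the list alone. S100a8 had 38 and 3 counts (ratio 0.212, counting interval 0.0419 to 0.668), the receptor Csf3r 30 and 1 (ratio 0.0895, counting interval 0.00219 to 0.538), and myeloperoxidase (Mpo) 143 ± 34.9 and 41.9 ± 59.2. Of 21 measured immediate early genes 5 were higher and 16 lower (gap -0.15, limma camera adjusted p = 0.403), and 2 passed limma over all genes. These were the AP-1 gene Fosl2 (14 and 0 counts, bound of 1.74-fold, limma adjusted p = 0.00622) and the mRNA decay factor Zfp36 (12 and 0 counts, bound of 1.49-fold, limma adjusted p = 0.00864). The stress factor Atf3 had 385 ± 189 and 119 ± 97.5, and the phosphatase Dusp1 186 ± 84.9 and 41.9 ± 59.2.

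Monocyte antigen presentation and NF-kB genes went both ways. Of 19 measured antigen presentation genes 10 were higher and 9 lower (gap 0.60, limma camera adjusted p = 0.348). The immunoproteasome subunits Psmb10 and Psmb9 had 227 ± 114 and 85.6 ± 56.7 in shScrmbl against 506 ± 143 and 155 ± 76.5 in shXbp1 libraries, the class I regulator Nlrc5 34.3 ± 28.8 and 82.0 ± 27.1, and the lysosomal protease Ctss 12128 ± 967 and 7363 ± 3621. Of 18 NF-kB and proinflammatory genes 6 were higher and 12 lower (gap 0.67, limma camera adjusted p = 0.710). Cxcl2 had 1184 ± 746 and 376 ± 31.0 and Nfkbiz 374 ± 154 and 139 ± 18.4. Ccl2 had 37.1 ± 26.6 and 214 ± 231, and Ccl7 had 1 and 10 counts (ratio 26.9, counting interval 3.82 to 1165).

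Genes at an unadjusted limma p under 0.05 were compared between cell types by one-sided Fisher's exact tests, 6 in all. No pair passed the test. Astrocytes and microglia shared 3 lower genes (H2-Aa, H2-DMa and Saa3) among 2901 tested in both, where 1.07 were expected (adjusted p = 0.531 by Fisher's exact test). Rps24 was the 1 shared higher gene. Genes chosen by edgeR gave another picture for that pair, with 21 shared lower genes where 5.65 were expected (Fisher's exact p = 7.9e-08, adjusted p = 4.7e-07; 145 and 113 genes). They included the myeloid genes Cd68, Cybb, Gpnmb, Lgals3 and Saa3, the class II genes H2-Aa, H2-Ab1 and H2-DMa, and Apoc2. Fisher's test takes genes as independent, whereas myeloid genes can move together with the share of myeloid cells. The labels also leave open whether both cell types came from the same mice. The p of this overlap therefore measures no spread between mice. Across genes, which are not independent replicates, Spearman correlations of the limma differences were -0.0026, -0.035 and 0.045.

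Marker genes were compared as mean log2 signal per library by exact two-sided permutation tests, 18 in all. A sorted cell's own markers were not always the highest list. In shScrmbl astrocyte libraries astrocyte markers averaged 5.78, microglia 6.52, oligodendrocyte lineage 7.44 and ependymal and choroid plexus markers 7.72. In shScrmbl monocyte libraries microglia markers averaged 8.70, monocyte and macrophage markers 8.45 and lymphocyte markers 7.90. Levels of different lists do not give shares of cells. Astrocyte markers averaged 5.78 ± 0.58 in shScrmbl and 6.90 ± 0.19 in shXbp1 astrocyte libraries (difference 1.12, exact p = 0.0286, the smallest possible, adjusted p = 0.257). Against all genes the groups overlapped. The levels were 0.09, -0.10, 1.04 and 1.90 in shScrmbl replicates 1 to 4 and 1.44, 1.29, 1.10 and 1.15 in shXbp1 replicates 1 to 4. Of 21 measured astrocyte markers 17 were higher, though limma camera did not call the list (gap 0.52, adjusted p = 0.0903). By edgeR 18 were higher (camera on counts adjusted p = 0.000341, and 0.334 with an estimated correlation). The bicarbonate transporter Slc4a4 had 11.1 ± 13.6 and 76.0 ± 24.1, the glutamate transporter Slc1a2 102 ± 95.1 and 207 ± 105, Slc7a10 83.0 ± 79.2 and 165 ± 79.2, and Cpe 45.6 ± 80.3 and 83.7 ± 21.9. Ependymal and choroid plexus markers averaged 7.72 ± 1.06 and 8.41 ± 0.50 (exact p = 0.286, adjusted p = 0.643), with 11 of 13 higher (gap 0.08, limma camera adjusted p = 0.664). Of these, Ttr had 234832 ± 35839 and 187553 ± 57085, Kl 335 ± 393 and 395 ± 112, Rarres2 114 ± 105 and 177 ± 79.9, and Rsph1 112 ± 56.5 and 162 ± 54.3. Microglia markers averaged 6.52 ± 1.36 and 6.64 ± 0.34 in astrocyte libraries, and quantile normalization turned the difference to -0.31. By edgeR 19 of these 20 markers were lower (median -0.80, camera on counts adjusted p = 0.00016, and 0.466 with an estimated correlation).

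In microglia libraries, monocyte and macrophage markers averaged 7.39 ± 1.09 with shScrmbl and 5.45 ± 0.66 with shXbp1 (exact permutation p = 0.0571, adjusted p = 0.257), and neutrophil markers 6.57 ± 0.44 and 4.41 ± 1.97 (exact p = 0.0286, the smallest possible, adjusted p = 0.257). The neutrophil difference was smaller on the count scale (median edgeR difference -0.67, camera on counts adjusted p = 0.233), and against all genes shXbp1 replicates 1, 2 and 3 lay at 0.12, -3.39 and -0.96 from the shScrmbl mean. Microglia markers themselves averaged 9.78 ± 0.25 and 9.87 ± 0.41 there. In monocyte libraries neutrophil markers averaged 6.41 ± 0.14 and 3.62 ± 0.01, and monocyte and macrophage markers 8.45 ± 0.40 and 7.81 ± 1.58. None of the 18 marker comparisons passed after adjustment. The smallest possible exact permutation p was 0.0286 in astrocytes and microglia and 0.333 in monocytes. No single comparison could therefore pass an adjustment over 18 tests, whatever its difference.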

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

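The tests of the pseudocount in monocytes, and of monocyte markers and of the share of each difference kept in microglia, were chosen after the results were seen. Thinning was added after the data were seen but before its own result, and the other tests were chosen before theirs. Each list level per library and each depth measure was looked at for a library that stood far from the others of its group of 4, by the gap to its nearest neighbour over the range of the group. Chance picks out about 1 in 20 such groups, and 6 of 84 stood out where 4.2 were expected. Astrocyte shScrmbl replicate 2 held 302003 counts while the others held 32842 to 50392. Neuron markers in astrocyte shScrmbl replicate 3 lay at -1.54 (log2, against all genes), with the others at -0.0956 to -0.0781. Cell cycle genes in astrocyte shXbp1 replicate 4 lay at -0.53, against 0.705 to 0.909 in the others. Homeostatic microglia genes in astrocyte shXbp1 replicate 1 lay at 1.25, against 0.552 to 0.589. Monocyte and macrophage markers in astrocyte shXbp1 replicate 2 lay at 0.33, against -1.49 to -1.19. Ttr made up 6.25% of counts in microglia shScrmbl replicate 1 and 1.69% to 2.07% in the other shScrmbl microglia. Whether list responses differed between cell types was tested by permuting hairpin labels within each cell type: of 57 comparisons 5 had an unadjusted exact permutation p under 0.05 and 0 passed after adjustment (lowest adjusted p = 0.339).

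Most monocyte genes called lower, Gdpd1, Nin and Fosl2 among them, were at 0 in both shXbp1 libraries. With the counts thinned to the shallowest library the median number of genes called lower over 20 draws was 0, and with a pseudocount of 20 it was also 0. The depth gap between the groups, and a pseudocount below the value of 1 count, may therefore have a part in the calls. The thinning and the pseudocount of 20 also ended the limma calls of Ccl17 and Apoc2, which had counts in both groups. Neither setting can thus tell such an effect from lost power. With no change at the real monocyte depths, limma with the main pseudocount called 0 genes in each of 10 simulations. The depth gap and pseudocount alone did not make such calls there, where each gene varied independently. The depth gap and the pseudocount do not explain the number of zeros: sampling at these depths gave 47.2 genes (SD 6.74) at 0 in both shXbp1 libraries and 101 were seen. The called genes had a median log2 difference of -1.92 with a pseudocount of 20 and -1.45 after thinning, but they were chosen because they were low, and 0 of them passed edgeR (178 genes of all tested had an unadjusted p under 0.05). For the excess of zeros, lower expression in monocytes of shXbp1 mice and variation between mice beyond sampling both stay open with 2 against 2 libraries.

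Antigen presentation genes such as H2-Aa and H2-DMa lay lower in shXbp1 astrocytes, and myeloid cells express them strongly. Without the library labelled shScrmbl replicate 2, which held the most myeloid RNA, the list still lay at -1.09 against other genes (limma camera adjusted p = 0.0284). The same step took the gaps of oxidative phosphorylation and ribosomal protein genes to -0.93 and -0.84, though their median edgeR differences were -0.02 and -0.02. It also left only shallow shScrmbl libraries, so this gap cannot decide whether that library was the sole cause. Fewer microglia and monocytes in all shXbp1 astrocyte libraries stays a candidate explanation. On the log scale the list lay below 32 myeloid markers by 1.36 standard errors (-1.36; list -0.68, markers -0.04, exact permutation p = 0.171), too little to tell, and by edgeR the medians were -0.85 for the list, -0.80 for microglia markers and -1.11 for monocyte and macrophage markers. A lower level within astrocytes could not be separated from this, because the sort gate is not given.

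Genes that edgeR called lower in microglia, such as Cybb, Hp, Lyz2 and Saa3, are strongly expressed by monocytes and macrophages. The 15 other monocyte and macrophage markers had a median edgeR log2 difference of -0.66, 14 of them lower, while homeostatic microglia genes had 0.42, with 19 of 20 higher. These values are in line with fewer monocytes or macrophages in the shXbp1 microglia libraries, from infiltration or from sorting, neither of which was tested. Without shScrmbl replicate 3 edgeR left 0 of the 12 calls, which 1 library as the source would give. With a library fewer the test also loses power, so this loss cannot tell these causes apart. Without any 1 library the called genes kept a median share of at least 0.857 of their log2 differences. That lowest share came without shScrmbl replicate 2. There Cybb went from -1.95 to -1.37, Hp from -3.06 to -2.22 and Cfb from -2.29 to -1.57. The median share, chosen after the results were seen, argues against 1 library as the only source for the 12 genes as a set. It does not cover each gene: Prss34 went from 1.94 to 0.73 without shXbp1 replicate 3. A change of expression within microglia stays open.

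Other splits of the same libraries were counted for astrocytes and microglia, 35 each, the real split included. In astrocytes 11 gave at least as many edgeR calls (real value 1, highest of the others 28) and 24 as many lists (3, highest 10). In microglia 6 gave as many edgeR calls (12, highest 29) and 4 as many lists (4, highest 6). Chance was not excluded for any of these 4 results. For limma the count says nothing, since with 0 real calls all 35 splits give as many in either cell type (highest of the others 0 in astrocytes and 3 in microglia). The astrocyte split with 28 edgeR calls set shScrmbl replicate 1 with shXbp1 replicates 1, 3 and 4 against the rest, and the microglia split with 29 set shScrmbl replicates 2, 3 and 4 against the rest. Both keep most hairpin labels, exchanging shScrmbl replicate 1 with shXbp1 replicate 2 in astrocytes and moving shScrmbl replicate 1 in microglia, and counts this far above the real ones point to a structure of the libraries whose source was not tested.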

How the results depend on the processing

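The pseudocount of 20, the thinned counts, edgeR as a result of its own and the count-based list and overlap tests were chosen after the data were seen. Counts of 10039 to 302003 per library limit what could pass, and for changed values below the cause was not tested unless a reason is given. Astrocyte genes changed by limma were 0 in the main test and 0 with each library left out, with 1 by edgeR and 1 with counts thinned to the shallowest library. Microglia genes changed by limma, 0 in the main test, were 11 by eBayes without trend and robust, 2 with quantile normalization, 12 by edgeR and 3 with thinned counts, and 0 to 3 with a library left out. Monocyte genes changed by limma, 101 in the main test, were 0 by eBayes without trend and robust, 0 with quantile normalization, 0 with genes above the median level (where the low genes are not tested), 0 with a pseudocount of 5, 0 with a pseudocount of 20, 0 with thinned counts, 1 by edgeR and 0 by DESeq2. They were 0 to 1163 with a library left out, where a lone library was assumed to vary like the other group. Genes called by edgeR in astrocytes (1) were 0 by DESeq2 and 0 to 8 with a library left out. Those in microglia (12) were 0 by DESeq2, 0 with genes above the median level and 0 to 23 with a library left out, and the 1 in monocytes was 0 by DESeq2, 0 above the median level and 0 to 61 with a library left out.

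Lists called in astrocytes, 3 in the main test, were 7 with array weights, 5 with quantile normalization, 1 with genes above the median level, 1 with a pseudocount of 5, 9 with a pseudocount of 20, 0 with an estimated correlation, 0 by fry, 11 on recovered counts, 1 with thinned counts, 9 at an adjusted p under 0.10, and 1 to 11 with a library left out. Lists called in microglia, 4 in the main test, were 0 with an estimated correlation, 0 by fry, 6 on recovered counts, 0 with thinned counts and 0 to 5 with a library left out. Lists called in monocytes, 2 in the main test, were 1 with quantile normalization, 0 with an estimated correlation, 0 by fry, 4 on recovered counts, 1 with thinned counts and 1 to 6 with a library left out. Overlaps past the test, 0 by limma, were 1 by edgeR.

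The Xbp1 difference in astrocytes, 0.12 by limma, was -0.0563 with quantile normalization, -0.12 with median centring, -0.0801 by edgeR, -0.13 by DESeq2 and -0.23 to 0.42 with a library left out. It ran from -1.90 to 1.67 in microglia and from -0.27 to 0.998 in monocytes with a library left out, and had no value for microglia above the median level, which Xbp1 does not reach. Other signs turned as well. In astrocytes Cxcl2 was -0.31 by edgeR and -0.11 by DESeq2, and Srgn -0.22 and -0.0184. Gaps of astrocyte lists were 0.0198 for oxidative phosphorylation and 0.0805 for ribosomal protein genes with quantile normalization. By fry, which does not compare with other genes, astrocyte means were 0.00653 for ribosomal protein, 0.25 for NF-kB and 0.19 for reactive astrocyte genes. The ER chaperone list in astrocytes ran from -0.00147 to 0.34 and the ependymal list from -0.42 to 0.57 with a library left out. Disease-associated microglia genes in microglia (gap 0.42) had -0.17 with quantile normalization, -0.13 above the median level, -0.0726 with a pseudocount of 20, -0.33 by fry, -0.23 on recovered counts and -0.16 with thinned counts, and NF-kB genes had 0.37 above the median level. In monocytes fry gave -0.36 for antigen presentation and -0.29 for NF-kB genes, and immediate early genes ran from -0.64 to 0.35 with a library left out. Marker differences turned to -0.31 (quantile normalization) and -0.0692 (median of members) for microglia markers and -0.60 (quantile normalization) for lymphocyte markers in astrocytes, and to -0.0386 (median) for microglia markers in microglia. In monocytes they turned to 0.11 and 0.24 for microglia, 0.16 and 0.13 for lymphocyte and 0.56 and 0.28 for oligodendrocyte lineage markers (quantile normalization and median).

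Libraries with the same number in both groups were treated as unpaired, and the labels do not settle this. Correlations of their deviations from the group means were 0.0475, 0.0644, 0.0131 and -0.00401 for astrocyte replicates 1 to 4. For microglia replicates 1 to 3 they were 0.0294, -0.00197 and 0.0576. Several libraries correlated best with their own number, though not every one did, so a pairing was not excluded. With 2 against 2 monocyte libraries all correlations have the same size (0.0756 or -0.0756) and cannot tell. With a replicate block limma called 0 astrocyte, 0 microglia and 112 monocyte genes, edgeR called 3 astrocyte genes (Apod, Lyz1 and Lyz2, not Apoc2), 24 microglia genes (all 12 of the main test among them) and 0 monocyte genes, and camera called 4, 4 and 2 lists. Xbp1 differences with the replicate block were 0.12, -1.90 and 0.37. The replicate block leaves out microglia shScrmbl replicate 4, which has no partner. Of the other values, 115 planned and 19 added ones of results that answer a comparison, and 2122 planned and 141 added ones of single genes and lists, kept their direction and side of the threshold.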

Other observations

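The test of Apoc2 was written before its result was seen, but Apoc2 was picked because it was low. Among gene groups not described so far, astrocytes had lower edgeR values of disease-associated microglia genes in 22 of 23 members, with Apoe at 3156 ± 1122 in shScrmbl and 1865 ± 669 in shXbp1 libraries (SD, n = 4 and 4) and the adaptor Tyrobp at 356 ± 272 and 174 ± 58.0; camera on counts called the list lower (adjusted p = 1.1e-05, and 0.45 with an estimated correlation) and limma camera did not (10 higher and 13 lower, adjusted p = 0.088). Interferon response genes were higher for 16 and lower for 10 of 26 members by limma (camera adjusted p = 0.133) and for 5 and 21 by edgeR (camera on counts adjusted p = 0.00832, downward, and 0.466 with an estimated correlation), with the tetherin gene Bst2 at 30.2 ± 11.3 and 68.4 ± 11.3. Cholesterol and fatty acid synthesis genes were higher for 11 of 17 (adjusted p = 0.503 by limma camera), the elongase Elovl5 having 18 and 6 counts and a log2 difference of -3.07 by limma. ATF4 and CHOP stress genes were higher for 6 of 15 (limma camera adjusted p = 0.143), with the glycyl-tRNA synthetase Gars at 64.1 ± 35.9 and 118 ± 24.7 and the folate enzyme Mthfd2 at 41.5 ± 36.4 and 6.47 ± 9.07. Oligodendrocyte lineage markers were higher for 4 of 12 (limma camera adjusted p = 0.088), with Trf, transferrin, at 2148 ± 1112 and 1227 ± 335. Neuron markers were higher for 5 of 6 (limma camera adjusted p = 0.428), with Stmn2 at 53.4 ± 46.1 and 103 ± 23.1. Endothelial and mural markers were higher for 5 of 7 (adjusted p = 0.503 by limma camera), with the lipid transfer protein Pltp at 79.0 ± 63.3 and 145 ± 31.5. Cell cycle genes were higher for 8 of 12 (adjusted p = 0.898 by limma camera), and classical and alternative myeloid genes for 5 of 8 and 2 of 6 by limma (camera adjusted p = 0.352 and 0.193) and for 0 of 8 and 1 of 6 by edgeR (camera on counts adjusted p = 0.0107 and 0.00051, downward, and 0.466 and 0.39 with an estimated correlation). Immediate early genes were higher for 7 of 16 by limma (camera adjusted p = 0.0856) and for 1 of 16 by edgeR (camera on counts adjusted p = 0.00166, downward, and 0.45 with an estimated correlation), with Klf4 among the lowest. No member of these lists passed limma over all genes or adjusted over the list alone, and by edgeR 1 ATF4 and CHOP gene, 1 immediate early gene and 1 alternative myeloid gene passed adjusted over the list alone.

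In microglia, alternative anti-inflammatory myeloid genes were lower for 7 of 8 members (limma camera adjusted p = 0.396, camera on counts 0.00143, and 0.374 with an estimated correlation), with the scavenger receptor Stab1 at 173 ± 17.5 in shScrmbl and 89.2 ± 96.4 in shXbp1 libraries. T, NK and B cell markers were lower for 5 of 8 (limma camera adjusted p = 0.677), Cd3g of the T cell receptor complex having 17 and 1 counts (ratio 0.195, counting interval 0.00468 to 1.25). In monocytes the same lymphocyte markers were higher for 9 of 16 (limma camera adjusted p = 0.183), with Cd3g at 473 ± 102 and 862 ± 290 (n = 2 and 2). Hspa5 had 1156 ± 271 and 1639 ± 194 in microglia and 928 ± 246 and 1191 ± 174 in monocytes. The ER chaperone list as a whole did not rise in microglia. Of its 21 measured members there, 7 were higher and 14 lower by limma (gap 0.13, limma camera adjusted p = 0.978), and 10 higher and 11 lower by edgeR. The mitochondrially encoded genes were not tested, since fewer than 5 were in any table. Lists that limma camera did not call had adjusted p of 0.254 to 0.978 in microglia and 0.183 to 0.943 in monocytes. Camera on counts with an estimated correlation called no list in any cell type (lowest adjusted p = 0.334 in astrocytes, 0.374 in microglia and 0.839 in monocytes).

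Apoc2 had lower values with shXbp1 in each of the 3 cell types. By edgeR the log2 differences were -3.11 in astrocytes (adjusted p = 0.0145), -1.82 in microglia (776 ± 722 and 290 ± 288, adjusted p = 0.0693) and -2.35 in monocytes (adjusted p = 0.333). A hypothesis is that Apoc2 is lower in myeloid cells of shXbp1 mice and reaches the astrocyte libraries with them, or is lower in each cell type. The test was of chance over all genes: among 2573 genes in all 3 tables, 1 of 100 random regroupings of the libraries gave some gene a combined difference of log2 counts as low as the -5.83 of Apoc2 (lowest -6.23), which argues against chance over all genes if the cell types came from different mice. The labels leave open whether they did, and libraries of the same mice would fall together more often than these regroupings allow. The macrophage gene Chi3l3, also called Chil3, was the one gene lower still (-7.21). Chi3l3 had edgeR differences of -2.33, -4.02 and -1.76, Lyz2 of -2.19, -1.44 and -1.13, Apoe of -0.76, -0.65 and -1.10, and the macrophage complement gene C1qa of -1.36, -0.09 and 0.44. Nothing here separates a cell's own Apoc2 from the share of macrophages in a library.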
